A study of Mus musculus with 13 samples.

How the data were processed

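Messenger RNA of single mouse macrophages was measured with a targeted panel of 500 genes, most of them immune-response genes, on the BD Rhapsody platform. In this method cells are caught in microwells with barcoded beads, and only the panel's transcripts are amplified and sequenced. Cells of different conditions were marked with antibody-borne sample tags and pooled on 1 cartridge. Each of the 13 cartridges is 1 library, and the library is the replicate throughout. Cells were never counted as replicates.

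The authors made 1 table per library with the BD Targeted Multiplex Rhapsody Analysis Pipeline, version 1.9, and state genome build mm10. The deposited tables hold counts, which are whole numbers of molecules per gene and cell after the pipeline's own correction of molecular identifiers, with no normalization. A deposited annotation table, whose unit is other (cell labels and no measurement), gives the sample tag, stimulus, time and macrophage type of each cell. Library 13 went through the pipeline at a later date than the other libraries, which the labels show. The annotation also names 3 further batches with 50720 cells, which were not used here.

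The tables hold 292864 barcodes. Of these, 250309 carried 1 sample tag and were kept, 24454 carried several tags and 18101 had no tag call, and both of the latter kinds were left out. Molecules were summed per library, macrophage type, stimulus and time, which gave 143 sums (pseudobulks) of at least 132 cells. Cells were not clustered, since the labels give 1 cell type.

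Levels are given as molecules per 10000 panel molecules. The panel is small, so a stimulus that raises abundant chemokine transcripts lowers the share of other genes. Counting intervals for a level are exact Poisson intervals, and those for a ratio are exact conditional binomial intervals, both at 95%. They cover counting error only and not the difference between cultures. A count of 0 allows up to 3 molecules. Folds against a group at 0 are given as a lower bound, with 3 molecules over the whole group as the floor.

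In M0 macrophages, counts were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) in R 4.3.3. The standard error of a log2 change is its size divided by the square root of the test's F. P-values were adjusted by the Benjamini-Hochberg method over the tested genes. A gene was called at an adjusted p under 0.05 and a log2 change of at least 1 in size. The first model had the 23 pseudobulks of unstimulated, 3 h and 8 h samples that at least 2 libraries hold, with no library term, 480 genes tested and 12 residual degrees of freedom (biological coefficient of variation 0.803). It served the comparisons with unstimulated cells and of 8 h with 3 h. The second model had the 13 pseudobulks at 3 h with library as a block, 476 genes tested and 4 residual degrees of freedom (0.335), and served the comparisons between stimuli. IFNb and a low LPS dose had 1 library at 3 h, and that lone sample was assumed to vary like the others. In the first model p-values measure the spread between libraries of a group, which is partly technical. Samples of 1 library count there as independent. In the second model they measure the scatter left after differences between libraries are taken out.

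Fixed gene lists were tested with fry of limma 3.58.1, which asks whether the genes of a list move on balance to one side, in 50 tests (10 lists, 5 stimuli) adjusted together. Only lists with at least 3 measured genes were tested. The list tests used the samples of the first model with no library term. They were not repeated with a library block or without whole libraries. No list of lymphoid, mast cell or reference genes had a measured member, the dendritic list had 1 (Xcr1), the cell-cycle list 1 (Ccnd1) and the neutrophil and progenitor list 2 (S100a8, Cd34). The macrophage list had 3 measured members (Adgre1, Cd163, Marco), of which 2 passed the filter, so it was not tested. For comparisons with 1 library on at least 1 side, the median ratio of a list was placed among 10000 random lists of like expression, without a test. Where the M0 side had several libraries, their molecules were summed.

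Named genes followed a rule. For each stimulus against unstimulated cells they are the 6 called genes with the largest rise and the 3 with the largest fall that moved the same way in every library, and the 3 largest changes of each fixed list. For pairs of stimuli they are the 4 largest called changes each way, and for 8 h against 3 h the 3 largest. For single libraries they are the 6 largest ratios each way among genes with at least 100 molecules, with the 3 largest of the lists that belong to the comparison. Samples, groups, lists, tests, thresholds, the naming rule and most alternatives were fixed before the data were examined. The text gives part of each set.

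Variation between cells and stimulus assignment used counts thinned to 300 molecules per cell, the depth that at least 81.8% of the cells of every M0 group at 3 h reached, and cells below it were left out. The Fano factor is the variance divided by the mean. Assignment used multinomial logistic regression (scikit-learn 1.9.0, inverse penalty 0.1) on up to 300 cells per stimulus and library. It was tested on a held-out library or on 5 parts of a library in turn, and scored by the mean share of right calls per stimulus. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures used matplotlib 3.10.9, and gene positions are those of GENCODE M21 on mm10.

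The steps were tested on simulated data. For LPS against unstimulated cells and for the lists, the simulated samples of a library shared no library difference. In the real data the unstimulated and LPS samples of library 13 correlated at r = 0.938, and the unstimulated samples of libraries 3 and 13 at 0.719. For LPS against TNF library differences were drawn at random, and whether they match the real ones was not tested. The shares called, also of unchanged genes and unmoved lists, therefore need not hold for the real libraries. For LPS against unstimulated cells, 2.42% of genes changed 2-fold were called, 16.6% of those changed 4-fold, 50.2% of those changed 8-fold and 69.8% of those changed 16-fold. Of genes left unchanged beside them, 0.44% were called, and none of 2339 in data without changes. For LPS against TNF the shares were 36.0%, 87.8%, 98.4% and 100%, with 1.88% of unchanged genes called and none of 2312 without changes. A list moved 4-fold was called in 20 of 20 simulations, and unmoved lists in 3 of 180 tests, adjusted over 10 lists and not over 50 tests. The ratio intervals covered the true ratio in 96.0% of simulated pairs.

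Alternatives were DESeq2's size factors within edgeR, panel totals alone, cell numbers as library size, no filter on low counts, the Wald test of DESeq2 1.42.0, only cells with at least 200 molecules, removal of the 2% of cells with the most molecules, a library block added or removed, unthinned counts, 150 cells per stimulus, and leaving out each library in turn. Chosen after the data were seen were leaving out the unstimulated cells of library 13, alone and with cell numbers as library size, and a fit of the 3 h and unstimulated samples alone.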

Results

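The data are molecule counts for 500 genes in mouse macrophages stimulated with immune ligands, and the comparisons ask how the response depends on the ligand, on time, on prior polarization and on genotype. Most samples were iMPDM, macrophages differentiated over 10 days from immortalized myeloid progenitors. They were left unpolarized (M0), or were treated for 24 h with 50 ng/mL IFN-gamma (M1) or 50 ng/mL IL-4 (M2). The stimuli were LPS at 100 ng/mL (a bacterial ligand of TLR4), TNF at 10 ng/mL, poly(I:C) at 50 ug/mL (PIC, a double-stranded RNA mimic), CpG DNA at 100 nM (a TLR9 ligand), IFNb at 500 U/mL, P3CSK (a lipopeptide ligand of TLR2) and a lower LPS dose (LPSlo). The doses of P3CSK and LPSlo are not stated. M0 samples came from libraries 7 (0.25 and 8 h), 8 (1 and 3 h), 11 (0.5 and 8 h), 12 (3 and 5 h) and 13 (3 h and unstimulated), and from library 3, which held unstimulated M0, M1 and M2 cells and M2 cells at 1 h. M1 samples came from libraries 4, 5 and 6 and M2 samples from libraries 1, 2 and 3. Bone marrow-derived macrophages (BMDM) at 8 h were from NOD Aire GW/+ mice (library 9) and from C57BL/6 wild-type and Nfkbia m/m mice (library 10). Total molecules ranged from 21370470 in library 3 to 103996711 in library 4, and the median per cell from 723 in library 13 to 5971 in library 4. Of the macrophage markers on the panel, Adgre1 (F4/80) had a median level across samples of 118 molecules per 10000 in M0, 85.1 in M1 and 255 in M2, Marco of 0.514, 0.0358 and 0.0351, and Cd163 of 0.0074, 0 and 0. The progenitor marker Cd34 lay at 9.99, 1.55 and 9.17, and at 0.0258 or less in BMDM, and the neutrophil marker S100a8 at 0.637, 0.110 and 0.888, and in C57BL/6 BMDM at 52.5 (wild type, highest 1298) and 40.4 (Nfkbia m/m, highest 1547).

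In M0 cells at 3 h, edgeR with the library block called genes in 9 of the 10 pairs of stimuli tested. The interferon gene Ifnb1 and the cytokine gene Il6 were among them. Pairs with IFNb or LPSlo had 1 library on that side, and without the block most of these 9 pairs had no called gene. LPS was measured in libraries 8, 12 and 13, P3CSK in 8 and 12, TNF, PIC and CpG in 8 and 13, IFNb in 8 and LPSlo in 12. Ifnb1 (chromosome 4, 88522025 to 88522774) was higher after LPS than after P3CSK by 8.00 ± 1.56 on the log2 scale (SE; adjusted p 0.00652, edgeR), with TMM-scaled levels of 13.1 ± 1.9 (SD, n = 3) and 0.0376 ± 0.0096 (SD, n = 2) per 10000. Against CpG it was higher by 5.67 ± 1.49 (adjusted p 0.0214). Il6 (chromosome 5, 30013114 to 30019981) was higher after LPS than after TNF by 6.24 ± 1.59 (adjusted p 0.0164) and than after PIC by 5.38 ± 1.52 (adjusted p 0.0303). The direction was the same in both libraries that allowed each comparison. Library 12 decided 2 of these calls, since without it the adjusted p became 0.058 for Ifnb1 against P3CSK and 0.057 for Il6 against PIC. By panel totals, Il6 lay at 118, 100 and 99.8 per 10000 after LPS in libraries 8, 12 and 13, at 17.8 and 13.4 after P3CSK and at 2.21 after IFNb. Of the libraries that held TNF and PIC, library 8 had far less Il6 than library 13, at 0.317 against 17.1 after TNF and 1.45 against 18.1 after PIC. Ifnb1 lay at 0.0987 in library 8 and 3.82 in library 13 after TNF, at 0.0846 and 1.77 after CpG, and at 13.8 and 6.97 after LPS. Log levels over genes after LPS and TNF correlated at r = 0.838 in library 8 and 0.949 in library 13. Every pair of LPS, TNF, PIC and CpG was more alike in library 13, and the cause was not tested.

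**Figure D1:**
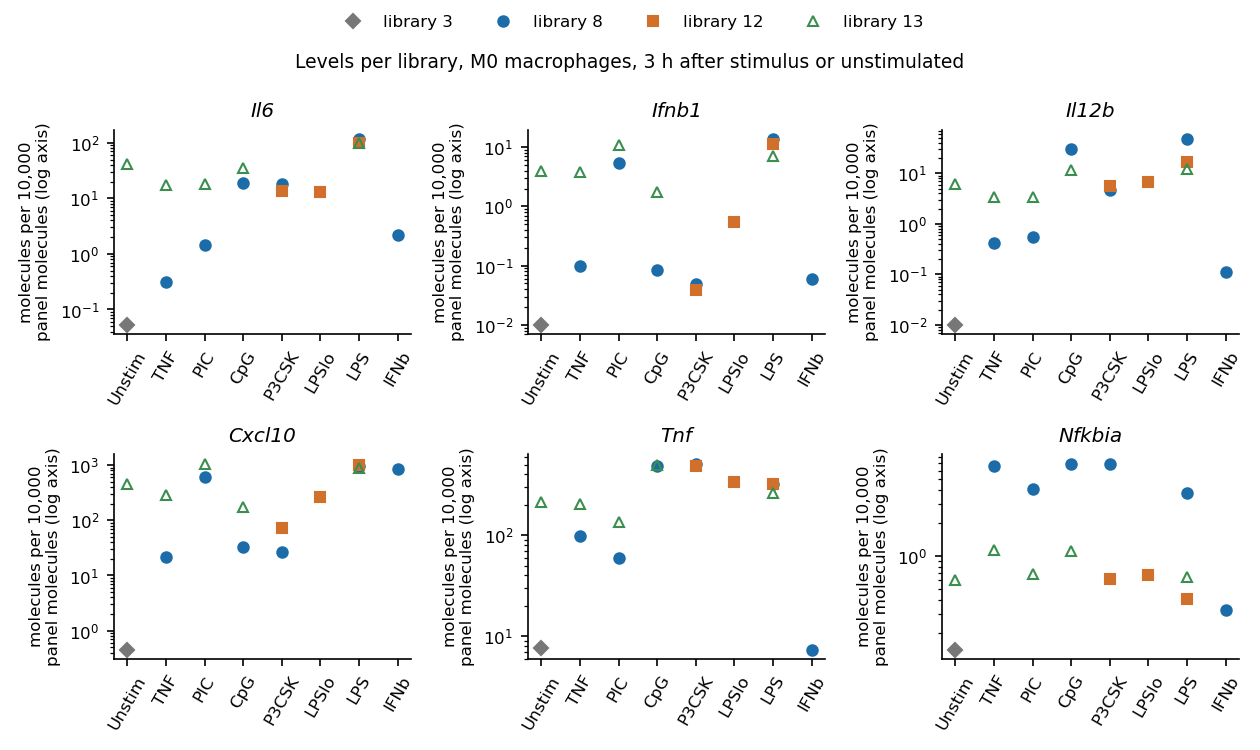
Levels of 6 transcripts in M0 cells at 3 h after each stimulus or without stimulus, in molecules per 10000 panel molecules on a log axis, with 1 point per library and values under 0.01 drawn at 0.01. Il6 lay between 99.8 and 118 after LPS in all 3 libraries, and the open triangles of library 13 lay at 41.6 for unstimulated cells, where library 3 lay at 0.0528.

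Differences between stimuli reached many of the 476 genes tested. LPS and TNF differed at 189 genes (101 higher after LPS), LPS and P3CSK at 154 (74 higher), LPS and PIC at 152 (72 higher) and LPS and CpG at 150 (68 higher). The balance of higher and lower genes depends on the scaling. In the same order, 65 of 276, 58 of 201, 51 of 197 and 59 of 191 called genes were higher with panel totals, and 129 of 159, 89 of 126, 140 of 149 and 89 of 118 with cell numbers as library size. Besides Ifnb1 and Il6, the largest rises in LPS cells were in U90926, Edn1 and Cxcl9 against TNF, in U90926, Edn1 and Ccl17 against PIC, in Cxcl9, Cxcl11 and Oasl1 against CpG, and in Tnc, Oasl1 and Lipg against P3CSK. U90926 was at 0 after TNF, which makes it at least 33.4-fold higher after LPS, and Tnc was at 0 after P3CSK (at least 3.96-fold). Among the genes lower after LPS were Dusp8, Kcnj2 and Egr2 against TNF, Prokr1, Plau and Trib3 against PIC, Flrt3, Gdf15 and Trib1 against CpG, and Mmp3, Marco and Pim2 against P3CSK. The counts rest on the library block, without which edgeR called none of these genes (71, 77, 58 and 52 at an unadjusted p under 0.05, in the order above), while DESeq2 with the block called 207, 162, 166 and 153. Without library 12 the count was 49 against PIC and 65 against P3CSK, and without library 13 it was 216 and 180.

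IFNb and the low LPS dose had 1 library each at 3 h, so counts against them assume that this lone sample varies like the other groups. LPS and IFNb differed at 258 genes (148 higher after LPS), PIC and IFNb at 202 (122 higher after PIC) and TNF and IFNb at 257 (148 higher after TNF), all in library 8 for IFNb. Without the library block these counts were 13, 0 (63 at an unadjusted p under 0.05) and 10. Higher after LPS than after IFNb were Ccl17, Il12b and U90926, and lower were Angpt1, Serpina3f, Iigp1 and Ifit1bl1. Serpina3f and its near-identical neighbour Serpina3g were among the 4 largest falls of TNF against IFNb (log2 changes of -9.07 and -7.94, adjusted p 7.24e-05 for both, edgeR), and how reads matching both genes were assigned is not stated. Ccl5 was higher after PIC than after IFNb by 4.84 ± 1.10 (SE; adjusted p 0.00882). Of the 10 pairs tested, CpG and P3CSK had the fewest differences, with 0 genes called by edgeR (2 at an unadjusted p under 0.05) and 0 by DESeq2. TNF and P3CSK differed at 13 genes, all lower after TNF (8 of 12 with panel totals, 34 of 51 with DESeq2), led by Marco, Ppfia3, Nfkbiz and Zc3h12a. That count was 1 with DESeq2's size factors, with cells of at least 200 molecules, without the top 2% of cells or without library 12, 48 (35 lower) without library 13, and 0 without the block (31 at an unadjusted p under 0.05) or with cell numbers as library size (83). LPS and LPSlo (library 12) differed at 77 genes (41 higher after LPS; 27 of 96 with panel totals and 31 of 41 with cell numbers as library size), among them Asap3 (0 after LPSlo, at least 9.27-fold), Plagl1, Ifit1bl1 and Ifit1 and, lower, Gdf15, Kcnj2 and Btg2. Without library 13 the count was 166, and without the block 0 (42 at an unadjusted p under 0.05).

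Unstimulated cells were held by libraries 3 and 13, and these differed so much that they limit every comparison with them. Tnf lay at 7.62 per 10000 in unstimulated cells of library 3 and at 216 in those of library 13, where LPS cells had 263. Cxcl10 lay at 0.453 and 449. Unstimulated cells of library 13 also had few molecules, with a median of 323.5 per cell. Against both libraries together, edgeR called 60 genes after LPS (14 higher, 46 lower) of 480, 24 after P3CSK (14 higher), 7 after CpG (2 higher), 3 after TNF (1 higher) and 0 after PIC (44 at an unadjusted p under 0.05), and DESeq2 called 134, 94, 91, 37 and 3. With panel totals edgeR called 55, 0 (101 at an unadjusted p under 0.05), 2, 0 (70) and 0 (41), and in a fit of 3 h and unstimulated samples alone, chosen after seeing the data, 2, 0 (89), 0 (97), 0 (50) and 0 (32). With a library block it called 104, 22, 38, 6 and 3, which shared 41 of the 60 genes after LPS, 6 of the 24 after P3CSK, 5 of the 7 after CpG and 1 of the 3 after TNF. Library 3 has only its unstimulated sample in this model, so the block fits that sample exactly. Calls kept or lost with the block, here and below, therefore rest on the unstimulated cells of library 13 alone. Without library 13 the counts were 169 (97 higher), 106, 88, 44 and 39. Without library 3 they were 2, 0, 1, 0 and 0, without library 8 they were 1, 0, 0, 0 and 0, and without library 12, 6 after LPS and 0 after P3CSK. The order of the stimuli by count is therefore not a measure of the size of their response.

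Genes called higher after LPS included the adhesion gene Sele, the proteinase Mmp14, the cytokine Il27, Rnd1 and Ccrl2. Sele (chromosome 1, 164048234 to 164057677) was at 0 in all unstimulated cells and at 0.38 ± 0.20 per 10000 after LPS (SD, n = 3), at least 27.1-fold higher (adjusted p 0.0098, edgeR). It was also at least 28.7-fold higher after CpG and at least 32.5-fold higher after P3CSK, and Mmp14 was at least 5.77-fold higher after LPS. Il27 rose by 3.91 ± 1.21 on the log2 scale (SE; adjusted p 0.0441), and by 7.83 without library 13, while its call was lost without library 3 (adjusted p 0.33), 8 (0.12) or 12 (0.13). Of the fixed list of feedback genes, Socs3 rose by 2.35 ± 0.67 (adjusted p 0.0347) and Tnfaip3 by 1.79 ± 0.46 (adjusted p 0.0232). The calls of both were lost without library 3, without library 8 (adjusted p 0.099 and 0.099) and without library 12 (0.09 and 0.083). Cxcl2 was called after P3CSK (log2 change 4.23 ± 0.98, adjusted p 0.0403). After LPS no gene was called higher without library 3 or without library 8, and 1 (Sele) without library 12, so Rnd1, Mmp14 and Ccrl2 also lost their calls there. With a library block Rnd1 and Tnfaip3 stayed called after LPS, while Sele (adjusted p 0.091 after LPS, 0.17 after CpG and 0.23 after P3CSK), Mmp14 (0.24), Il27 (0.13), Ccrl2 (0.12), Socs3 (0.061) and Cxcl2 (0.14 after P3CSK) lost their calls. After P3CSK, Sele and Cxcl2 also lost theirs with panel totals (0.061 for both) and with cell numbers as library size (0.059 for both).

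The phosphatase gene Dusp6 (chromosome 10, 99263231 to 99267489) fell after every ligand for which genes were called, with log2 changes of -6.41 ± 0.91 after LPS (SE; adjusted p 0.00141, edgeR), -5.14 after TNF, -7.19 after CpG and -6.35 after P3CSK, and was lower in every library compared. The LPS call held without each library in turn (adjusted p 0.00094 to 0.034) and with a library block (0.0019), which ended the TNF call of Dusp6 (0.053). Its calls after TNF, CpG and P3CSK were also lost with cell numbers as library size (log2 changes of -3.50, -5.84 and -4.14, adjusted p 0.30, 0.098 and 0.078) and without library 8 (0.34, 0.20 and 0.15). Those after TNF and P3CSK were lost with panel totals (0.13 and 0.054) and without library 3 (0.33 and 0.085), and that after P3CSK without library 12 (0.098). Also lower after LPS were Gpr35 (-4.91), Myc (-3.54 ± 0.76, adjusted p 0.0102), Il4ra (-2.45), Gclm (-3.05) and Tlr7 (-1.63). Thbs1 was lower after TNF, Fos and Bambi after CpG, and Lratd2 and Bambi after P3CSK, where the block ended the call of Bambi (adjusted p 0.13). These are changes in the share of panel molecules. With cell numbers as library size the median log2 change of all genes after LPS moved from 0.20 to 2.73, and edgeR called 132 genes, 130 of them higher. Per cell, Dusp6 still had a log2 change of -4.23 (adjusted p 0.034), that of Myc was -1.77 (adjusted p 0.15) and that of Tlr7 was 1.02 (adjusted p 0.47).

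Of the fixed lists, fry found chemokine genes up after LPS (9 genes, median log2 change 2.22, adjusted p 0.037), with cytokine genes (11 genes, 3.28, adjusted p 0.048) and feedback genes (10 genes, 2.01, adjusted p 0.013). With panel totals the calls of the cytokine and feedback lists after LPS were lost (adjusted p 0.0569 for both). Immediate-early genes were down after LPS (15 genes, median -2.38), PIC (-1.29, adjusted p 0.0098) and CpG (-1.49, adjusted p 0.043). With cell numbers as library size all 3 of these calls were lost (median -0.02, -0.51 and -0.38, adjusted p 0.997, 0.788 and 0.788), and with panel totals those after PIC (0.0998) and CpG (0.261). Feedback genes were up after TNF (1.22, adjusted p 0.030), CpG (1.92, adjusted p 0.0098) and P3CSK (1.79, adjusted p 0.0098), and with cell numbers as library size the calls after TNF (0.157) and CpG (0.052) were lost. That made 9 of 50 tests, none of which was repeated with a library block. The interferon-stimulated list did not pass after LPS (14 of 14 genes higher, median 3.80, adjusted p 0.070) or PIC (14 of 14, 3.89, adjusted p 0.0997), and without the unstimulated cells of library 13 it did, at 0.0066 and 0.0098, as it did with cell numbers as library size, at 0.020 and 0.036. Adjusted over the list alone, edgeR called 6 immediate-early genes lower and 2 feedback genes higher after LPS, against 4 and 2 over all genes tested. In none of the stimuli did the lists for IFN-gamma polarization (adjusted p 0.397 or more), IL-4 polarization (0.457 or more), oxidative stress (0.397 or more), signalling components (0.202 or more) or type I interferons (0.526 or more) pass. With cell numbers as library size the IFN-gamma list passed as up after LPS (median 4.67, adjusted p 0.029) and the IL-4 list as up after P3CSK (3.60, adjusted p 0.029). Without the unstimulated cells of library 13, fry found the IL-4 list down after all 5 stimuli (adjusted p 0.000058 to 0.00065, though the median after P3CSK was 0.30), against library 3 alone, where unstimulated M0 cells shared the cartridge with M2 cells and had 0.312 Arg1 molecules per cell beside 0.00996 in library 13. It also found signalling components up after TNF, PIC, CpG and P3CSK (0.0016 to 0.046). The sign of the test and of the median differed for the IL-4 list and the type I interferon list after LPS, and for the chemokine list and the type I interferon list after TNF.

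The time course in M0 cells joined libraries, and each of 0.25, 0.5, 1 and 5 h came from 1 library. Each library held only 2 of the times, so steps within a library compare times on 1 cartridge and other steps also compare libraries. After LPS, Cxcl2 lay at 62.8 per 10000 at 0.25 h, 434 at 0.5 h and 534 at 1 h, then at 185, 177 and 38.0 in the 3 libraries at 3 h, at 133 at 5 h, and at 107 and 38.4 at 8 h. Within libraries Cxcl2 went from 62.8 at 0.25 h to 107 at 8 h (library 7), from 434 at 0.5 h to 38.4 at 8 h (library 11), from 534 at 1 h to 185 at 3 h (library 8) and from 177 at 3 h to 133 at 5 h (library 12). Il12b lay at 1.78 at 1 h and at 48.2, 16.5 and 12.1 at 3 h. Ifit3, an interferon-stimulated gene, lay at 16 at 1 h, at 141, 149 and 67.4 at 3 h and at 221 at 5 h, and after PIC reached 475 at 5 h. Nfkbia, which encodes the NF-kB inhibitor IkBa, lay at 17.9 at 0.5 h and 13.0 at 1 h. At 3 h it lay at 3.76 in library 8 but at 0.404 in library 12 and 0.639 in library 13, a spread between libraries that is wider than most differences between stimuli for this gene. Between 3 h and 8 h, edgeR called 14 genes after LPS (11 higher), led by Hp, Lcn2 and Plpp1, while Rnd1, Noct and Mmd fell. The count was 0 without library 7, 8, 11 or 12 (46, 94, 61 and 98 at an unadjusted p under 0.05) and 35 without library 13. No gene was called after TNF, PIC, CpG or P3CSK (43, 43, 67 and 58 at an unadjusted p under 0.05, and 18, 22, 47 and 24 called by DESeq2).

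**Figure D2:**
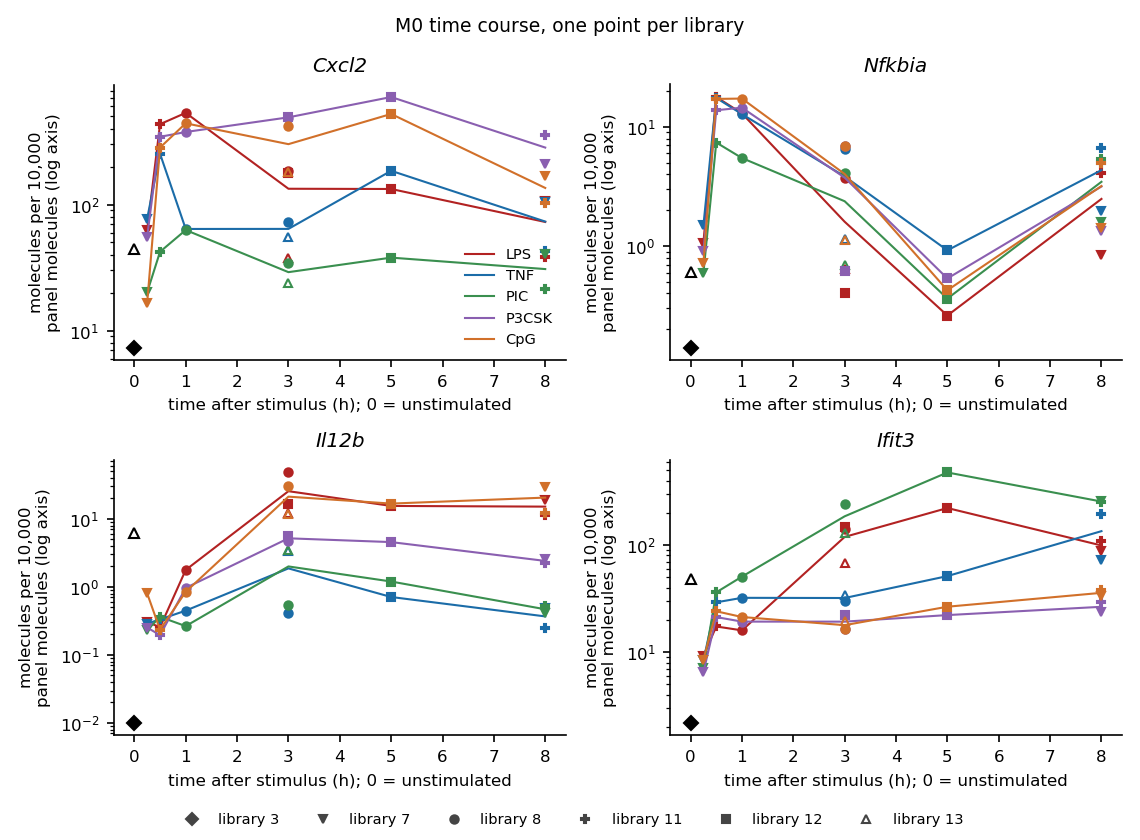
Levels of 4 transcripts in M0 cells over time after 5 stimuli, in molecules per 10000 panel molecules on a log axis, with point shapes for libraries (open triangles for library 13), black points for unstimulated cells and lines through the mean over libraries, values under 0.01 being drawn at 0.01. Nfkbia lay at 17.9 at 0.5 h after LPS and at 3.76, 0.404 and 0.639 in the 3 libraries at 3 h.

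Polarization was compared within library 3, which held all 3 unstimulated states, without replicates. In M1 cells the measured IFN-gamma list (7 genes with enough counts) had a median ratio to M0 of 15.7, above 99.89% of random lists of like expression, and interferon-stimulated genes had a median ratio of 15.6. Cxcl9 was 372-fold higher (counting interval 103 to 3070), Slamf8 198-fold (150 to 266), Iigp1 172-fold (93.4 to 360) and Irf1 18.1-fold (17.1 to 19.3). Gbp2b was highest, at 514-fold (176 to 2497), and Cd14 was lower, at a ratio of 0.199 (0.191 to 0.207). In M2 cells the IL-4 list had a median ratio of 20.8 (6 of 7 genes higher), above all random lists. Tmem26 was 75.5-fold higher (36.4 to 188), Chil3 53.9-fold (46.8 to 62.4), Retnla 38.4-fold (34.2 to 43.3) and Arg1 37.5-fold (35.1 to 40.1), and Thbs1 and Cd14 had ratios of 0.0309 and 0.0611. The M0 and M1 cells of this cartridge carried Arg1 at 4.08 and 3.64 per 10000 beside 153 in M2 cells, and whether that is background of the cartridge was not tested.

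**Figure D3:**
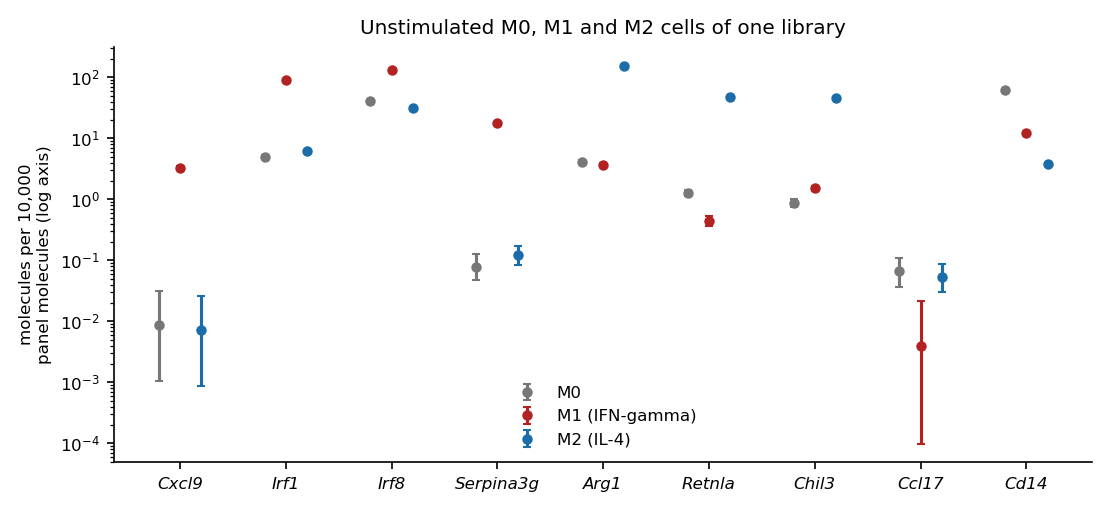
Levels of 9 transcripts in unstimulated M0, M1 and M2 cells of library 3, in molecules per 10000 panel molecules on a log axis, with exact Poisson intervals at 95% as bars. Irf1 lay at 91.1 in M1 cells and 5.03 in M0 cells, and Arg1 at 153 in M2 cells and 4.08 in M0 cells.

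Cytokine transcripts were lower in M2 than in M0 cells at 3 h after LPS, CpG, PIC, TNF and P3CSK, with 1 M2 library (library 1) that held no M0 cells. The M0 side of the ratios was the sum of molecules over libraries 8, 12 and 13, as far as they held the stimulus. After LPS, library 13 gave 19112681 panel molecules, library 8 4907417 and library 12 3783866. After PIC, library 13 gave 10002209 and library 8 2248699. Ratios to each M0 library alone are not given. The median ratio of cytokine genes to M0 was 0.444 after LPS, 0.169 after CpG, 0.130 after PIC, 0.220 after TNF and 0.0646 after P3CSK, at the 0.47th, 0th, 0th, 0.65th and 0th percentile of random lists. After IFNb it was 0.820 (25th percentile) and without stimulus, in library 3, 0.613 (20.8th). Against unstimulated cells of library 3, the median log2 rise of cytokine genes after LPS was 5.99 in M2 and 5.11 to 5.39 in the M0 libraries, while after P3CSK it was 1.65 and 4.91 to 6.00. Interferon-stimulated genes had a median ratio of 0.539 after LPS and 1.11 after P3CSK. In M1 cells (library 5), the IFN-gamma list stayed higher than in M0 cells after LPS (median ratio 2.63), and cytokine genes had ratios of 0.580 after LPS (12.0th percentile), 0.561 after CpG (14.8th), 0.249 after TNF (1.27th), 0.264 after PIC (0.50th) and 0.234 after P3CSK (0.70th). M1 cells given LPS had H2-Eb1 20.2-fold and Irf8 13.9-fold higher than M0 cells. State and library coincide in these comparisons.

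In wild-type C57BL/6 BMDM, 8 h of LPS raised cytokine genes to a median ratio of 10.3 over unstimulated cells and interferon-stimulated genes to 4.74, and P3CSK raised cytokine genes to 33.8. These medians are over the 9 and 10 cytokine genes with enough counts, and over all 11 the median log2 changes were 2.65 and 4.14. The unstimulated samples of this library held 148 and 132 cells. The neutrophil marker S100a8 ranged from 19.5 to 1298 per 10000 over the wild-type samples and from 11.4 to 1547 over those of the other genotype. The annotation names 1 of the 2 genotypes MM, which was taken to be Nfkbia m/m from the title of the library. These cells had less Nfkbia after each stimulus. The ratio to wild type was 0.256 after LPS (0.217 to 0.300), 0.0786 after TNF (0.0544 to 0.111), 0.130 after PIC (0.0890 to 0.184) and 0.158 after P3CSK (0.137 to 0.182), with 204 and 652 molecules behind the LPS ratio. Without stimulus there were 3 and 11 molecules, too few to tell a difference at this depth. In these genotype comparisons, list medians of feedback, interferon-stimulated and cytokine genes lay between 0.755 and 1.35. Without stimulus the cytokine list had too few genes with enough counts and was left out. The lowest were cytokine genes after PIC (0.755, 6 of 9 lower, 1.83rd percentile) and interferon-stimulated genes after P3CSK (0.832, 9 of 13 lower, 4.37th). The highest was that of feedback genes after PIC (1.35, 8 of 10 higher, 84.2nd). The largest differences were in single genes, and Cd55 was higher in Nfkbia m/m cells in all 6 comparisons, from 7.25-fold (4.27 to 13.1) without stimulus to 25.1-fold (20.1 to 31.5) after PIC. Vcam1 was 4.61-fold higher after LPS and 5.84-fold after P3CSK. Each genotype was in 1 library, so these differences were not tested against the spread between animals.

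**Figure D4:**
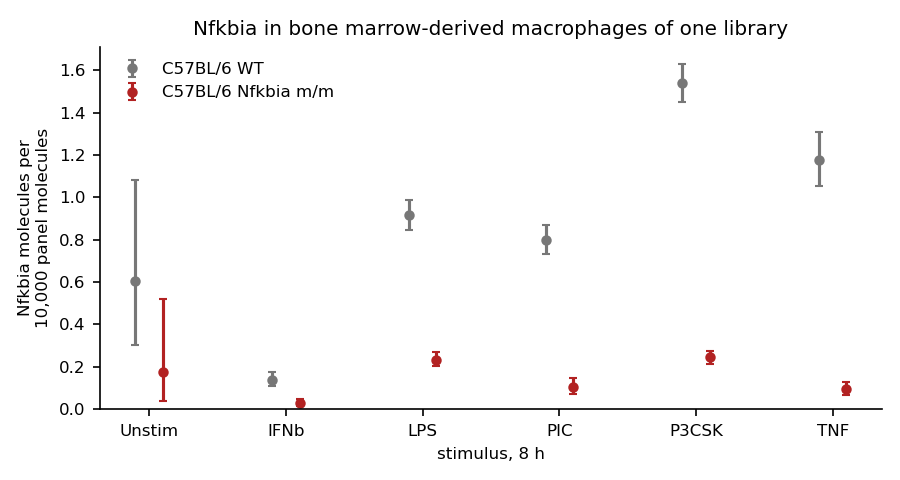
Nfkbia in wild-type and Nfkbia m/m BMDM at 8 h, in molecules per 10000 panel molecules, with exact Poisson intervals at 95% as bars. After LPS the levels were 0.915 and 0.234.

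NOD Aire GW/+ BMDM are annotated as healthy or sick, without a definition. Aire itself is not on the panel. List medians of sick over healthy cells were near 1, from 0.871 to 1.13. The lowest was that of cytokine genes after LPS, with 8 of 10 genes lower, at the 0.92nd percentile of random lists. Chil3 was lower in sick cells in all 6 comparisons, with ratios from 0.0809 (0.0602 to 0.107) after LPS to 0.350 (0.216 to 0.542) after PIC. S100a8 had a ratio of 0.0936 after LPS and 2.07 after PIC. The low LPS dose was compared with the full dose within cartridges. In library 12 the full dose raised interferon-stimulated genes 7.05-fold over the low dose at 3 h (median, 14 of 14 genes) and 2.06-fold at 5 h, and Ifnb1 21.3-fold (17.5 to 26.3) at 3 h. In library 11 the median ratio was 0.848 at 0.5 h (12 of 14 genes lower) and 0.955 at 8 h. That of cytokine genes at 0.5 h was 0.792 (9 of 10 lower, 0.91st percentile). Cells of 8 h shared this cartridge, and late transcripts at 0.5 h may be their free RNA. Among these are Ifit1, Ifit2, Ifit3, Ifit3b, Mx1, Mx2, Oasl1, Rsad2 and Cmpk2 of the interferon-stimulated list. Their amounts per cell differed between stimuli by 1.11-fold (Rsad2) to 1.32-fold (Ifit1). The ratio of 0.848 therefore cannot be read as an effect of dose. Whether background also entered the cytokine ratio was not tested.

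Single cells differed within a stimulus. At 300 molecules per cell, 65.5% ± 5.4 of LPS cells had an Il6 molecule (SD, n = 3 libraries) and 16.1% ± 3.3 an Ifnb1 molecule, while 96.8% had Tnf. In IFNb cells of library 8, with the same number of molecules per cell, 6.32% (counting interval 5.39 to 7.34) had an Il6 molecule. The Fano factor was 7.17 ± 0.59 for Il1b, 4.54 ± 0.53 for Il6 and 1.85 ± 0.37 for Ifit3. No test of these values was run. LPS had 3 libraries and any other stimulus at most 2. Within a library, single cells could be assigned to the sample of their stimulus from their thinned profiles. Training and test cells of a stimulus came from the same library and time. Other differences between the samples of a library could therefore also help these calls. Right calls averaged 85.2% in M0 cells (library 8), 84.7% in M1 cells (library 5) and 84.2% in M2 cells (library 1), where chance is 16.7% and shuffled labels gave 15.7% to 16.9%. IFNb cells were recalled at 98.7% to 100% and LPS cells at 93.7% to 99%. CpG cells (64.3% to 75.7%) and P3CSK cells (65.3% to 73.7%) were less often called right, and most of their wrong calls were for each other. Within libraries 12 (3 stimuli) and 13 (4 stimuli), right calls were 83.8% and 84.3%. Tested on a library not used for training, right calls were 53.5% in library 8 (5 stimuli, chance 20%), 95.3% in library 12 (2 stimuli, chance 50%) and 45.8% in library 13 (4 stimuli, chance 25%). Shuffled labels gave 24.1%, 55.2% and 24.2% there. Of CpG cells in library 8, 91.0% were called P3CSK, and of PIC cells in library 13, 91.7% were called LPS. Each of these stimuli was trained on a single library, and without library 12 the value for library 8 was 72.9% (4 stimuli).

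**Figure D5:**
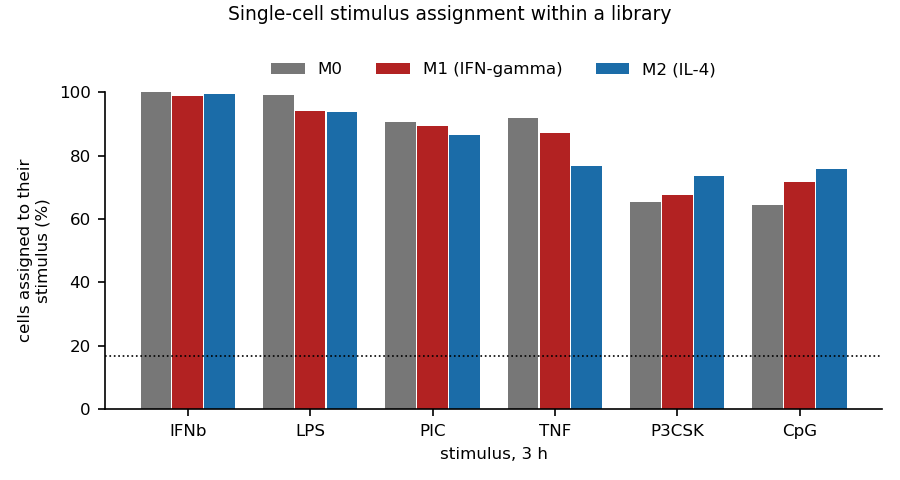
Percent of cells of each stimulus whose stimulus was called right by a classifier trained and tested within a library, for M0 (library 8), M1 (library 5) and M2 (library 1) cells at 3 h, 6 stimuli, 300 cells each. IFNb cells were recalled at 98.7% to 100% and CpG cells at 64.3% to 75.7%.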

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

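All 8 tests in this part, and their thresholds, were chosen only after the results they weigh were seen, and those of library 13 replaced earlier versions.

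The unstimulated M0 cells of library 13 carried inflammatory transcripts, and 3 explanations were set against each other at 300 molecules per cell in the 539 cells that reach this depth (465 were left out). Free RNA alone should give every cell about the same share. The median Fano factor of 22 interferon-stimulated and cytokine genes was 2.61, above the 1.5 set for free RNA. It was 2.12 for the same genes in TNF cells of library 11 at 0.5 h. Those cells had been stimulated and carried 5.79 Tnf molecules of 300 on average, so they may hold induced transcripts of their own. Their value is no measure of free RNA alone, and the test cannot tell. The limit for rejecting free RNA was raised after both values were seen, from 2, under which free RNA alone would have been rejected, to 2 times the value of library 11. Stimulated cells carrying the wrong tag should reach the level of stimulated cells, and 70.1% of the cells (378) did, against 2.37% of unstimulated cells in library 3 (69 of 2906), 99.5% of LPS cells and 49.3% of TNF cells. Of the 378 cells, 29.6% were assigned to LPS, 34.9% to PIC, 26.2% to CpG and 9.26% to TNF, beside 37.6%, 33.5%, 24.0% and 4.99% of the stimulated cells in the library. This fits wrong tags, but a mix of free RNA could give the same shares. A culture that was active before harvest, the biological explanation, should raise even the least active cells. The lower 50% of cells had 25.7 such molecules of 300, 8.35 times the 3.08 of library 3, which free RNA could also give, so the test cannot tell.

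The first versions of these tests gave other values. For free RNA the share of cells at the LPS 10th percentile was 0.679 of the Poisson share over 11 genes, but in 5 of them this threshold lay at or under the mean of the unstimulated cells. For wrong tags 94.4% of cells passed, but so did 65.9% in library 3, where chemokine transcripts are also high. For an active culture the ratio was 1.05, on sums that included those chemokines. The tests were replaced for these reasons, after their values were known.

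Late transcripts were found in library 11 as early as 0.5 h, where 8 h cells shared the cartridge. Late genes were chosen for a low amount at 1 h beside 3 h after LPS in library 8. Over 35 late genes the amount per cell at 0.5 h was 8.07% of that at 8 h (median, interquartile range 6.23% to 10.3%), which fits free RNA of the 8 h cells. Cells of 8 h with a wrong tag could give the same, and this was not tested. Early induction should differ between stimuli, but the highest stimulus was 1.30 times the lowest in the median gene, against 39.1 in library 8 at 3 h. This speaks against early induction only for genes already chosen as little induced by 1 h, so that choice partly fixed the outcome. Ccl5 stood at 19.3% of its 8 h amount, above the interquartile range. Only Trim21 was higher (24.5%), which had 23.2% of its 8 h amount at 0.25 h in library 7 and so transcripts of its own, as had Snn (15.5%, with 16.3% in library 7). The next, Rsad2, stood at 14.9% (3.07% in library 7). Ccl5 thus lies above the genes that compare best, and whether it fits free RNA cannot be told from 1 gene in 1 library. Low levels at 0.5 h in library 11 are therefore likely to include transcripts of the 8 h cells, whether as free RNA or through wrong tags.

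The 46 genes lower after LPS than in unstimulated cells could reflect the panel totals or the libraries compared. Per cell, 97.8% of them were also lower within library 13, and 78.3% (36 of 46) in libraries 8 and 12 against library 3. The rest of the 46 were lower there in share but not per cell, so for them the fall is one of share only. These libraries also differ in molecules per cell, with 7402 and 6163 after LPS in libraries 8 and 12 and 766 in library 3. All of them were in the fit that chose the genes. The test therefore cannot tell how much of the fall composition explains. Within library 13, which held both conditions, 100% were lower per 10000 molecules. But library 13 was part of the fit that chose these genes, and all 60 called genes had the same sign in every library, so this test is void and a difference between libraries stays open.

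Library 7 lay far from the other 4 M0 libraries in the share of barcodes without a tag call (23.1%) and of tagged cells with under 200 molecules (24.4%). Chance picks out about 1 in 20 groups in this way for each measure, and 7 measures were looked at. The first value only just passed (gap over range 0.712, limit 0.710). No cause was tested.

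Some lists had median log2 changes of opposite sign in macrophage types given the same stimulus. The changes are from unstimulated cells, at 3 h (M0, M1, M2) or 8 h (BMDM). No minimum size was set, and a value near 0 is an absent change, not an opposite one. These differences were not tested, and M0 changes refer to library 3 alone. Leaving out library 13 here was chosen after the list was seen: 8 comparisons of M0 with M1 or M2 are opposite without it and 6 with it, where opposite means in every M0 library. With it, as the mean over libraries, M0 chemokines after IFNb move by -0.84, interferon-stimulated genes after P3CSK by -0.69 and cytokine genes after IFNb by -1.24, so M0 then sides with M1, M1 and M2. Chemokines moved by -1.28 in M1 against 1.11 in M0 and 1.37 in M2 after IFNb, by -0.87 against 1.92 and 1.5 after PIC, and by -0.83 against 1.74 and 1.30 after TNF. Interferon-stimulated genes did not move in M1 after CpG (-0.0046), against 2.89 in M0 and 3.48 in M2. After P3CSK they moved by -0.53 in M1 against 1.97 in M0 and 4.01 in M2. M1 cells had these genes high before the stimulus. Immediate-early genes moved by 0.36 in M2 against -0.68 in M0 and -1.72 in M1 after P3CSK, and by 0.27 against -0.46 and -0.77 after TNF. Cytokine genes moved by -0.31 in M2 against 0.08 in M0 and 1.04 in M1 after IFNb.

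In BMDM, chemokines after LPS moved by 0.49 in Nfkbia m/m and by -0.51 in wild-type cells, cytokine genes after TNF by 0.62 and -0.41, and interferon-stimulated genes after P3CSK by -0.026 and 0.49. Cytokine genes after TNF moved by -0.46 in sick and 0.50 in healthy NOD cells. Over the genes with enough counts, cytokine genes after TNF had ratios of 1.54 and 1.15 and interferon-stimulated genes after P3CSK of 1.04 and 1.57, so neither pair is opposite there. None of these differences was tested, and the wild-type and Nfkbia m/m unstimulated samples were small. Barcodes of library 13 without a tag call, which no comparison used, held a median of 426.5 molecules, more than its unstimulated cells.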

How the results depend on the processing

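The alternatives that leave out unstimulated cells of library 13, and the fit of 3 h and unstimulated samples alone, were chosen only after the results were seen. Of 1214 gene results under alternatives, 843 kept direction and call, 369 lost the call and 2 reversed. Of 27 list results, 18 kept it, 8 lost it and 1 reversed, and of 1578 ratios 1072 kept within their interval, 500 moved and 6 reversed. Where no cause is named, the cause was not tested. Depth limits genes of low level most, and in unstimulated BMDM even Nfkbia.

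Against unstimulated cells, DESeq2's Wald test called 134 genes after LPS, 37 after TNF, 3 after PIC, 91 after CpG and 94 after P3CSK, and also 148 for LPS against LPSlo, 51 for TNF against P3CSK, and for 8 h against 3 h 84 (LPS), 18 (TNF), 22 (PIC), 47 (CpG) and 24 (P3CSK). Its size factors in edgeR gave 12 after CpG, 1 for TNF against P3CSK, and 4 (CpG) and 1 (P3CSK) for 8 h against 3 h. Panel totals gave 0 after TNF (70 at an unadjusted p under 0.05), 2 after CpG, 0 after P3CSK (101) and 9 for LPS at 8 h against 3 h. Cell numbers as library size gave 132 after LPS, 0 after TNF, CpG and P3CSK (75, 131 and 164), 41 for LPS against LPSlo, 0 for TNF against P3CSK (83) and 0 for LPS at 8 h against 3 h (54). They moved the median log2 change of all genes to 2.73 after LPS, 1.31 after TNF, 1.17 after PIC, 1.59 after CpG and 2.35 after P3CSK, from 0.20, 0, 0.16, 0 and -0.13. A library block, with which only library 13 informs the unstimulated side, gave 104 after LPS, 6 after TNF, 3 after PIC and 38 after CpG. Without the block the pairs LPS with TNF, PIC, CpG, P3CSK and LPSlo gave 0 (71, 58, 52, 77 and 42), as did PIC with IFNb (63) and TNF with P3CSK (31), while LPS with IFNb gave 13 and TNF with IFNb 10. TNF against P3CSK gave 1 with cells of at least 200 molecules and 1 without the top 2% of cells. Dropping the filter moved no count by more than 1.5 times.

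Without unstimulated cells of library 13 the counts were 137 (LPS), 49 (TNF), 34 (PIC), 83 (CpG) and 69 (P3CSK), and with cell numbers as library size also 0 (TNF, 76 unadjusted), 3 (PIC) and 23 (CpG). The 3 h and unstimulated samples alone gave 2 after LPS and 0 after TNF, CpG and P3CSK (50, 97 and 89).

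Leaving out 1 library at a time gave 1 to 169 after LPS, 0 to 44 after TNF, 0 to 39 after PIC, 0 to 88 after CpG and 0 to 106 after P3CSK. Pairs gave 155 to 237 (LPS, TNF), 49 to 216 (LPS, PIC), 115 to 142 (LPS, CpG), 65 to 180 (LPS, P3CSK), 222 to 320 (LPS, IFNb), 166 (LPS, LPSlo), 225 (PIC, IFNb), 269 (TNF, IFNb) and 1 to 48 (TNF, P3CSK), and LPS at 8 h against 3 h gave 0 to 35. A side left with 1 library was assumed to vary like the others. Pairs without library 8 have no residual degrees of freedom and were not run, and a library block cannot be fitted for 8 h against 3 h.

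Called lists numbered 1 (CpG), 4 (P3CSK) and 0 (TNF) with cell numbers, 1 (CpG), 2 (LPS) and 0 (PIC) with panel totals, and 5 (CpG, P3CSK, PIC) and 4 (TNF) without unstimulated cells of library 13. For immediate-early genes after CpG fry's direction reversed with cell numbers (adjusted p 0.788), while their median stayed at -0.38.

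Reversed genes were Tlr7 after LPS (log2 change 1.02 with cell numbers, 0.54 with library 13 unstimulated cells also left out), Nfkb1 after IFNb in wild-type BMDM (ratio 1.04 with cell numbers, 1.36 with TMM) and in Nfkbia m/m BMDM (1.21 with TMM), Nfkbie after IFNb in wild-type BMDM (1.16 with TMM), and Dusp1 after LPS in NOD BMDM (1.39 healthy, 1.28 sick, with cell numbers). Il27 at 5 h over 3 h in library 12 was 1.36 with cell numbers.

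Unthinned counts, being deeper, gave shares of 87.3% (Il6) and 49.1% (Ifnb1) and Fano factors of 139 (Il1b) and 35.2 (Ifit3). Leaving out libraries gave 62.6% to 67.9%, 14.3% to 17.5%, 6.95 to 7.50 and 1.67 to 2.04. Assignment with unthinned counts gave 91.8% (library 8), 91.1% (5), 89.9% (1), 90.9% (12) and 87.4% (13), and 57.1% for library 8 held out. With 150 cells it gave 82.6% (5), 79.7% (1) and 48.3% (8 held out). Leaving out a training library gave 72.9% to 100% (8), 97.3% (12) and 58.1% (13), with fewer stimuli.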

Other observations

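No test in this part was run as a hypothesis, and the values below were picked out after the results were seen. Genes raised by IL-4 were found in the unpolarized cells that shared a cartridge with M2 cells. In library 3 the amount per M0 cell was 2.22% of that per M2 cell for Arg1, 2.17% for Retnla, 1.54% for Chil3, 1.10% for Tmem26 and 2.67% for Slc7a2. In M1 cells it was 3.23% for Arg1, 1.26% for Retnla, 4.41% for Chil3, 1.61% for Tmem26 and 4.44% for Slc7a2. Unstimulated M0 cells of library 13, which held no M2 cells, had 0.00996 Arg1 molecules per cell against 0.312 in library 3, and no Retnla.

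Nfkbia differed between libraries for every stimulus at 3 h that several libraries held. After TNF it lay at 6.56 per 10000 in library 8 and 1.14 in library 13, after CpG at 6.94 and 1.12, after PIC at 4.07 and 0.689, and after P3CSK at 6.90 in library 8 and 0.621 in library 12.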
